A study of Mus musculus with 2 samples.

How the data were processed

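Single-cell T cell receptor (TCR) sequencing was done on 2 libraries from subcutaneous YUMMER1.7 tumors, a UV-irradiated mouse melanoma line, grown in C57BL/6J mice. Per the labels, 1 tumor was left untreated and 1 received a single combination of anti-PD-1, anti-CSF1R and agonistic anti-CD40 antibodies (TTx), and each tumor was 1 library. Per the labels' protocols, tumors were digested, sorted into CD45+CD3+, CD45+CD3- and CD45-CD3- cells and recombined at 2:1:1, 10000 cells were loaded per condition, and V(D)J libraries were made with a 10x Genomics 5' kit. The recombination was to set the proportion of T cells loaded, so the number of T cell barcodes is not a measure of T cell density in a tumor.

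The deposited table of each library listed assembled TCR contigs, 1 per row, with a cell barcode, the V, J and C gene, the CDR3 (the junction that contacts antigen) and raw counts of reads and of unique molecular identifiers (UMIs), per the file headers. The submitters' processing notes name Cell Ranger 5.0.1 and the mm10 build. The V(D)J reference version and the settings used are not given in the sources used here. Every contig in both deposited files was marked as belonging to a called cell and as high confidence, so barcodes below the cell call were not analysed here. Contig length, also deposited, is in bases. Neither file named a D gene or TRBC2 on any contig, and every contig with a TRBJ2 gene had an empty C gene. An entry named TRBV12-2+TRBV13-2 appeared as a V gene. All 66 of its productive contigs had a CDR3 that began CASG, as did all 6 of TRBV13-2, while 0 of 47 TRBV12-2 contigs did. It was kept as its own entry, and counting it as TRBV13-2 was an alternative chosen after seeing the data. All read counts were even numbers, for a reason not given in the sources used here. The largest sum of reads over a barcode was 79736 in the untreated library and 79478 in the TTx library, so read totals sat near a common ceiling and UMIs were used as the measure of depth.

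A T cell barcode was a called cell with at least 1 productive TRA or TRB contig. The dominant chain of a barcode was its productive contig with the most UMIs, with ties broken by reads. The clonotype of a cell was the V gene, J gene and CDR3 nucleotide sequence of its dominant TRA and TRB, and cells lacking either chain were left out. Gene usage was the share of cells whose dominant chain used a gene. TRAV genes were joined into families by their first number, and CDR3 features (length, cysteines, and hydropathy of the residues left after the outer parts, each the whole-number part of the length over 3, are removed) were taken over clonotypes of each chain (V gene, J gene and CDR3 nucleotides). To compare libraries of different size, TTx cells were drawn without replacement to the number of untreated cells 10000 times, and the median and central 95% range of the draws are given. With at least 2 cells a clonotype was called expanded. Doublets were not removed, because the files hold no gene expression. Barcodes with 2 or more productive TRB or 3 or more productive TRA chains were called doublet-like and left out in an alternative.

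With 1 tumor per condition there is no replicate and no test between conditions, and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals and counts of barcodes exact Poisson 95% intervals. A count of 0 is given with the share that 3 counts would make. All of these cover counting error only, not the variation between mice. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The functions were tested on simulated contig tables of the size of each library with known clones, chain losses and V genes, and all 10 quantities compared were recovered exactly. Of the 144 V and J names on productive chains, 143 matched a RefSeq gene symbol of the GRCm38.p6 assembly (mm10), which gave the coordinates; the joined entry did not.

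Clonotype definition, gene groups, receptor markers and the rule for named genes were fixed before the data were examined. Named genes were, for TRAV families, TRAJ, TRBV and TRBJ, the 5 with the highest share of cells in each library and the 3 with the largest difference in each direction among genes seen in 5 or more cells; ties were broken by the share in the other library and then by name. The rule gave 34 genes. Named clonotypes were the 5 largest of 2 or more cells per library and those seen in both libraries. The alternatives were a minimum of 2 or 3 UMIs per contig, doublet-like barcodes left out, no cell or confidence filter, full-length contigs only, barcodes thinned to 3 TCR UMIs, other clonotype definitions, clonotypes in place of cells, and all productive chains in place of the dominant one.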

Results

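TCR contigs were recovered from 1 untreated YUMMER1.7 tumor and 1 tumor collected 24 hours after TTx, both on day 8 after tumor initiation. TTx was given on day 7 and combined 50 µg of agonistic anti-CD40, 200 µg of anti-CSF1R and 200 µg of anti-PD-1. CD40 is the activating receptor of antigen-presenting cells, CSF1R is the receptor that maintains macrophages, and PD-1 is an inhibitory receptor of T cells. The comparison asks how the T cell receptors found in a tumor differ shortly after this treatment. Each condition was 1 tumor, and the intervals given with shares cover counting error only. The untreated library held 123 contigs with 497 UMIs, and the TTx library held 2068 contigs with 11107 UMIs. Reads in the TTx contigs were 10.9 times those in the untreated contigs.

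The TTx library gave many more T cell barcodes than the untreated library. There were 769 in the TTx library (95% Poisson interval 716 to 825) and 63 in the untreated library (48.4 to 80.6), a ratio of 12.2 (exact interval 9.43 to 16.0). All 63 and all 769 barcodes had at least 1 productive chain. TCR UMIs per barcode had a median of 8 (interquartile range 5 to 12) in the TTx library and 5 (3.5 to 7.5) in the untreated library. Productive TRB contigs had a median of 6 UMIs (3 to 9) after TTx and 4 UMIs (3 to 6) without treatment, and productive TRA contigs had medians of 3 (2 to 5) and 1.5 (1 to 3). Reads per barcode had a median of 76134 in the untreated library and 69728 in the TTx library, both near the ceiling of the read totals. Per the labels' protocols both tumors were sorted and loaded in the same way, and with 1 tumor each the difference in yield has no replicate check.

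The TRB chain was found in nearly all barcodes of both tumors, and the TRA chain was found less completely. TRB was present in 96.8% of untreated barcodes (95% interval 89.0 to 99.6) and 89.2% of TTx barcodes (86.8 to 91.3). TRA was present in 25.4% (15.3 to 37.9) and 54.2% (50.6 to 57.8). Both chains were present in 14 of 63 untreated barcodes, or 22.2% (12.7 to 34.5), and in 334 of 769 TTx barcodes, or 43.4% (39.9 to 47.0). When each barcode was thinned to 3 TCR UMIs, leaving out 6 untreated and 43 TTx barcodes with fewer, the expected share with both chains was 15.0% and 30.1%. More than 1 productive TRB was seen in 12.7% of untreated barcodes (5.65 to 23.5) and 10.0% of TTx barcodes (7.98 to 12.4). More than 1 productive TRA was seen in 3.17% (0.387 to 11.0) and 6.50% (4.86 to 8.48).

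Expanded clonotypes were found in the TTx tumor. Of its 334 cells with both chains, 104 (31.1%, 95% interval 26.2 to 36.4) belonged to 21 clonotypes of 2 or more cells, and there were 251 clonotypes in all. In the untreated tumor, 0 of 14 paired cells shared a clonotype, where 3 cells would make 21.4%. That is no upper limit on expansion, because 14 cells drawn from a tumor with expanded clonotypes often share none, as shown next. Drawn down to 14 cells, the TTx library had a median of 0 cells in expanded clonotypes (central 95% range of the draws 0 to 4), so the paired cells could not show a difference in expansion at this depth. The TRB chain alone, which was recovered from more cells, gave 2 of 61 untreated cells in shared chains (3.28%, 0.400 to 11.3) and 262 of 686 TTx cells (38.2%, 34.5 to 41.9). Drawn down to 61 cells, the TTx library had a median of 13 cells in expanded TRB chains (6 to 21) and 52 distinct chains (46 to 57), where the untreated library had 2 cells and 60 chains. The largest TTx TRB chain, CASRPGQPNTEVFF, was in 53 cells, 39 of them without a TRA. Free RNA of that chain in barcodes of other cells was not excluded, and no draw left the chain out. The TRA chain alone gave 4 of 16 untreated cells in shared chains and a median of 2 of 16 drawn TTx cells (0 to 6). The ranges describe drawing cells from 1 TTx tumor and leave out the variation between tumors.

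**Figure D1:**
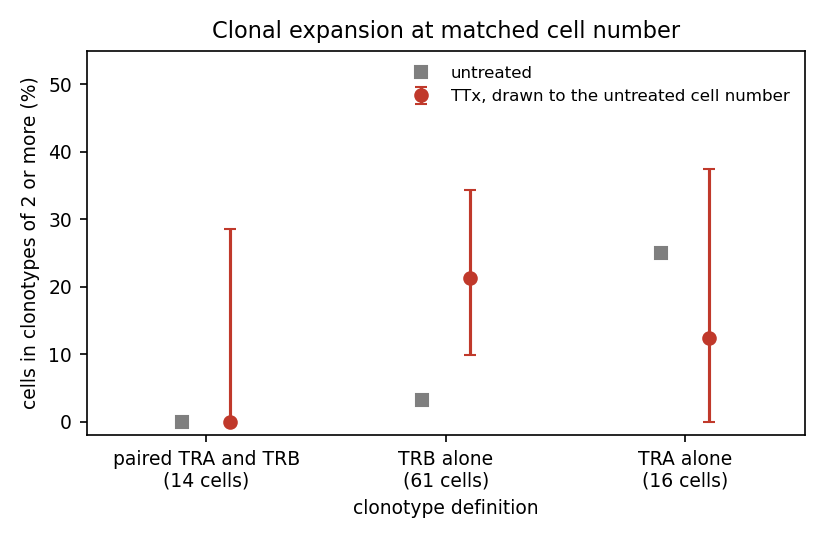
Share of cells (%) in clonotypes of 2 or more cells, by clonotype definition. Squares are the untreated library. Circles are the median over 10000 draws of TTx cells to the untreated cell number, with bars for the central 95% range of the draws. For TRB alone, the untreated value of 3.28% lay below the range of the TTx draws, 9.84% to 34.4%, and for the other definitions it lay within the range. The TTx draws kept the chain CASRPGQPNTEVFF, for which free RNA in other barcodes was not excluded.

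The most frequent TTx chains used TRBV14, TRBV20, TRBV3, the joined TRBV12-2+TRBV13-2 entry and TRBV19. The TRB chain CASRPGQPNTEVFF (TRBV14, TRBJ1-1) was the dominant TRB of 53 of 686 cells, or 7.73% (95% interval 5.84 to 9.98). The next were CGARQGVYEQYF (TRBV20, TRBJ2-7) in 26 cells, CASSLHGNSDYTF (TRBV3, TRBJ1-2) in 18 cells, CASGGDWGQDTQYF (joined entry or TRBV13-2, TRBJ2-5) in 16 cells by 1 nucleotide sequence and 18 cells by CDR3, and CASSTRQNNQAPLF (TRBV19, TRBJ1-5) in 15 cells. Among paired clonotypes, 3 held 12 cells each, or 3.59% of paired cells (1.87 to 6.19). The first joined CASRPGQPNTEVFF to the TRA chain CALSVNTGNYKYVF (TRAV12-2, TRAJ40). The other 2 shared the TRB chain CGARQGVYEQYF, with the TRA chain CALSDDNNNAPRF (TRAV6-7-DV9, TRAJ43) in 1 and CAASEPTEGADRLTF (TRAV7-4, TRAJ45) in the other. If these 2 are 1 clone with 2 TRA chains, which was not decided, the dominant-chain rule split it. The largest paired clonotype would then be above 3.59%. The fourth and the fifth were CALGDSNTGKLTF (TRAV6-6, TRAJ27) with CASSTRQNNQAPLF in 9 cells and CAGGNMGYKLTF (TRAV7D-3, TRAJ9) with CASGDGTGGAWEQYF in 8 cells. In the untreated tumor the only repeated TRB was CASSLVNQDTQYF (TRBV3, TRBJ2-5), in 2 cells, and the repeated TRA chains were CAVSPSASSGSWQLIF (TRAV7-3, TRAJ22) and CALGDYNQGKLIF (TRAV6N-7, TRAJ23), in 2 cells each. Each of these TRA chains made up 12.5% of the 16 untreated TRA cells (1.55 to 38.3).

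**Figure D2:**
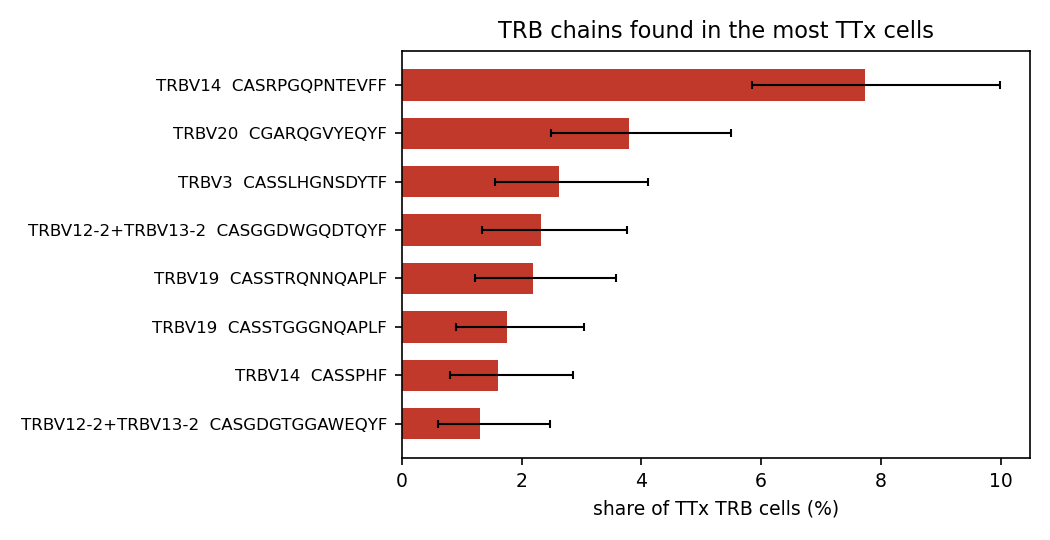
The 8 TRB nucleotide sequences found in the most TTx cells, each with its V gene and CDR3, as a share (%) of the 686 TTx cells with a TRB chain. Bars are shares and lines are exact 95% binomial intervals for counting error. The chain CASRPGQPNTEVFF reached 7.73%, and the next, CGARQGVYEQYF, 3.79%.

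The tumors shared no barcode, no paired clonotype and no TRB CDR3. They shared 2 TRA CDR3 amino acid sequences. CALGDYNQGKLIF (TRAV6N-7, TRAJ23) was the dominant TRA of 2 of 16 untreated cells and 11 of 417 TTx cells (2.64%, 1.32 to 4.67), with different nucleotide sequences in the tumors. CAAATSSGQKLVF (TRAV14D-1, TRAJ16) was found in 2 untreated cells and in 4 TTx cells (0.959%, 0.262 to 2.44). It was encoded by 2 nucleotide sequences in the untreated tumor, 1 of which was the nucleotide sequence found in the TTx tumor. In the untreated tumor each of these contigs rested on 1 UMI, while in the TTx tumor they had a median of 4 UMIs, and carry-over between the libraries was not excluded.

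TRBV usage was led by different genes in the tumors, with wide intervals in the untreated one. TRBV14 (chr 6, 41135167 to 41135616, mm10) was used by 12.1% of TTx cells (9.75 to 14.8) and 4.92% of untreated cells (1.03 to 13.7). Of the 83 TTx cells with TRBV14, 53 carried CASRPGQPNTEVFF. TRBV3 was used by 11.2% of TTx cells (8.96 to 13.8) and 8.20% of untreated cells (2.72 to 18.1). TRBV19 (chr 6, 41178589 to 41179048) was used by 8.60% (6.61 to 11.0) and 3.28% (0.400 to 11.3), and TRBV20 (chr 6, 41188273 to 41188977) by 6.56% (4.82 to 8.68) and 1.64% (0.0415 to 8.80). The opposite order was seen for TRBV16 (chr 6, 41151791 to 41152230), at 7.43% of TTx cells (5.59 to 9.66) and 13.1% of untreated cells (5.84 to 24.2). TRBV15 (chr 6, 41141211 to 41141658) stood at 3.35% (2.14 to 4.99) and 9.84% (3.70 to 20.2), TRBV29 at 3.94% (2.61 to 5.68) and 9.84% (3.70 to 20.2), and TRBV1 at 4.08% (2.73 to 5.85) and 8.20% (2.72 to 18.1). For each of these genes the intervals of the libraries overlapped. Counted once per clonotype, TRBV14 was 4.45% of TTx and 5.0% of untreated TRB chains, which turned its order, and TRBV20 was 4.03% of TTx chains. Over the 22 TRBV entries seen, shares in the libraries correlated across genes with a Pearson r of 0.44 and a Spearman rho of 0.56, and genes are not independent replicates. Over the alternatives the Pearson r ran from 0.33 (at least 3 UMIs per contig) to 0.65 (clonotypes counted once).

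**Figure D3:**
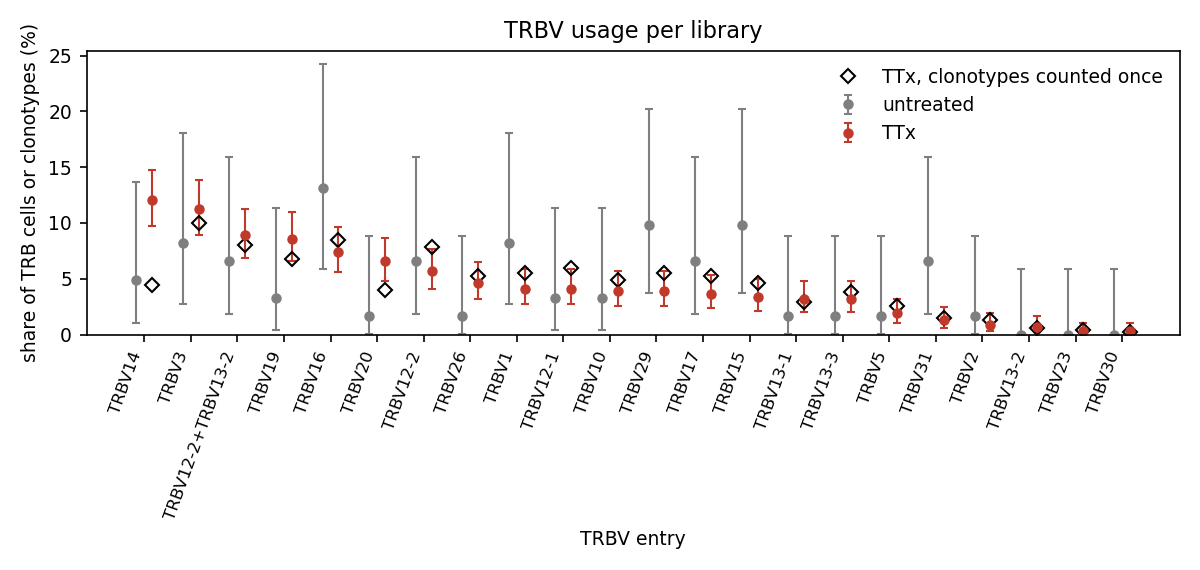
Share (%) of TRB cells using each TRBV entry, ordered by the TTx share. Filled circles are cells of the untreated (grey, 61 cells) and TTx (red, 686 cells) libraries with exact 95% binomial intervals for counting error, and open diamonds are TTx clonotypes counted once. TRBV14 was 12.1% of TTx cells and 4.45% of TTx clonotypes, so the diamond lies below the interval of the cells.

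The TRBV13 family, known by antibody as Vβ8, was used by 7.14% of TTx cells (5.33 to 9.33) and 3.28% of untreated cells (0.400 to 11.3) without the joined TRBV12-2+TRBV13-2 entry. That entry alone was 8.89% (6.87 to 11.3) and 6.56% (1.82 to 15.9). Counted as TRBV13-2, it brought the family to 16.0% and 9.84%. The TRBV12 family was used by 9.77% of TTx cells (7.65 to 12.2) and 9.84% of untreated cells (3.70 to 20.2).

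Most TRB chains of both tumors used the TRBJ2 cluster, the downstream J cluster of the locus. Its share was 61.1% of TTx cells (57.3 to 64.7) and 75.4% of untreated cells (62.7 to 85.5), and that of the TRBJ1 cluster was 38.9% (35.3 to 42.7) and 24.6% (14.5 to 37.3). Within the TRBJ1 cluster, TRBJ1-1 (chr 6, 41533864 to 41533911) stood at 13.1% of TTx cells (10.7 to 15.9) and 3.28% of untreated cells (0.400 to 11.3), and at 7.84% when TTx clonotypes were counted once. The chain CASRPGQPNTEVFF, for which free RNA was not excluded, made up 53 of the 90 TTx cells with TRBJ1-1. Those 53 were also part of the 267 TTx cells of the TRBJ1 cluster. TRBJ1-4 was used by 5.98% (4.32 to 8.02) and 1.64% (0.0415 to 8.80), and TRBJ1-6 by 2.04% (1.12 to 3.40) and 6.56% (1.82 to 15.9). TRBJ2-7 (chr 6, 41543810 to 41543856) was the most used J gene of the TTx tumor, at 21.7% (18.7 to 25) against 13.1% (5.84 to 24.2). TRBJ2-5 led in the untreated tumor, at 18.0% (9.36 to 30.0) against 11.2% after TTx (8.96 to 13.8). TRBJ2-1 followed at 16.4% of untreated cells (8.15 to 28.1) and 8.89% of TTx cells (6.87 to 11.3). TRBJ2-3 stood at 13.1% and 8.60%, and TRBJ2-4 at 8.20% and 6.12%. TRBC1 was named on 24.6% of untreated and 38.3% of TTx dominant TRB chains. TRBC2 was named on none, so the C genes could not be compared beyond what the J clusters show.

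TRA usage rested on 417 TTx cells and 16 untreated cells. TRAV6 was the most used family in both tumors, at 23.5% of TTx cells (19.5 to 27.9) and 4 of 16 untreated cells (7.27% to 52.4%). TRAV7 stood at 18.2% (14.6 to 22.3) and 18.8% (4.05 to 45.6), and at 11.7% when TTx clonotypes were counted once. With at least 2 UMIs per contig TRAV7 led in the untreated tumor, at 33.3% (7.49 to 70.1) beside 22.2% for TRAV6 (2.81 to 60.0). TRAV12 was used by 39 TTx cells, or 9.35% (6.74 to 12.6), TRAV8 by 26, or 6.24% (4.11 to 9.0), and TRAV5 by 11, or 2.64% (1.32 to 4.67). None of these 3 was seen in the 16 untreated cells, which allows a share of up to 18.8%. TRAV9 was at 8.87% and 12.5%, TRAV13 at 6.71% and 6.25%, TRAV14 at 6.00% (3.92 to 8.72) and 18.8% (4.05 to 45.6), and TRAV4 at 5.04% and 12.5%, TTx first in each case. The leading TTx J genes were TRAJ31 at 7.43%, TRAJ43 at 7.19%, TRAJ23 at 6.95%, TRAJ27 at 6.47% and TRAJ22 at 6.00%, and TRAJ45 stood at 5.28%. TRAJ22 (chr 14, 54197248 to 54197307) was the most frequent in the untreated tumor, with 3 of 16 cells, ahead of TRAJ16, TRAJ23 and TRAJ9 with 2 each. With doublet-like barcodes left out, TRAJ22, TRAJ16, TRAJ23 and TRAJ9 were level there at 13.3%. TRAJ16 was at 1.44% and TRAJ9 at 4.56% in the TTx tumor. The untreated values of TRAJ16 and TRAV14 were not separate. Both TRAJ16 cells, and 2 of the 3 TRAV14 cells, carried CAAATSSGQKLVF at 1 UMI each, where carry-over between the libraries was not excluded. TRAJ31 was seen in 1 untreated cell, and TRAJ27, TRAJ43 and TRAJ45 in none, which allows up to 18.8%. With TTx clonotypes counted once, TRAJ27 was 3.28%, TRAJ43 was 2.55% and TRAJ45 was 1.46%. With at least 2 UMIs per contig, TRAJ16, TRAJ9, TRAJ31 and TRAV13 were seen in no untreated cell. With at least 3, TRAV14 was seen in none either and stood at 6.67% of TTx cells, so the order of the tumors turned for TRAV14, TRAJ16 and TRAJ9. At that minimum the untreated interval for TRAV14 ran up to 40.96% and held the TTx share, so the turned order lay within counting error. Every interval for an untreated TRA gene overlapped its TTx interval.

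By position in the locus, TRAJ2 to TRAJ20 made up 24.2% of TTx cells (20.2 to 28.6) and 37.5% of untreated cells (15.2 to 64.6). TRAJ21 to TRAJ40 made up 53.5% (48.6 to 58.3) and 56.2% (29.9 to 80.2), and TRAJ41 to TRAJ61 made up 22.3% (18.4 to 26.6) and 6.25% (0.158 to 30.2). Genes of the duplicated TRAV region, named with a D or an N, were used by 43.4% (38.6 to 48.3) and 50.0% (24.7 to 75.3). These shares depended on the UMI minimum. With at least 2 UMIs per contig, TRAJ2 to TRAJ20 made up 22.2% of untreated cells (2.81 to 60.0) and 25% of TTx cells. With at least 3, it made up 14.3% of untreated cells (0.361 to 57.9) and 27.8% of TTx cells. TRAJ21 to TRAJ40 then made up 85.7% (42.1 to 99.6) and 48.9%, and the D or N genes 42.9% (9.9 to 81.6) and 44.4%, untreated first. Few untreated TRA cells were left at these minimums. Each untreated interval held the TTx share, so these values do not show a difference between the tumors. With clonotypes counted once, TRAJ21 to TRAJ40 made up 50% of untreated and 56.9% of TTx chains.

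Invariant and unconventional receptors were rare or not detected. A single TTx cell carried the invariant NKT chain, TRAV11 joined to TRAJ18 with the CDR3 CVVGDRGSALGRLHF, which recognises lipid on CD1d. It was 0.240% of TTx TRA cells (0.00607 to 1.33), rested on 1 UMI, and was found with the TRB chain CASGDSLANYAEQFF of the joined entry. No untreated cell of 16 carried it, which allows up to 18.8%. The MAIT chain, TRAV1 joined to TRAJ33, which recognises vitamin B metabolites on MR1, was seen in 0 of 417 TTx cells (up to 0.719%) and 0 of 16 untreated cells (up to 18.8%). No productive TRG, TRD or immunoglobulin contig was listed in either library among these barcodes, which were defined by a productive TRA or TRB chain, so this sets no limit on the share of such cells.

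TRB CDR3 averaged 14.4 ± 1.27 amino acids in the untreated tumor (SD over 60 clonotypes of 1 tumor) and 13.9 ± 1.45 in the TTx tumor (SD over 472 clonotypes of 1 tumor). The SD is the spread of single clonotypes, and the difference between the tumors was not tested. TRA CDR3 averaged 13.6 ± 1.45 (14 clonotypes) and 13.6 ± 1.36 (274 clonotypes), and 14.3 and 13.7 with at least 2 UMIs per contig, untreated first. Mean Kyte-Doolittle hydropathy of the central part of the TRB CDR3 was -0.97 ± 1.09 and -1.11 ± 1.00, untreated first. A cysteine inside the TRB CDR3 was found in 7 of 60 untreated clonotypes (11.7%, 4.82 to 22.6) and 28 of 472 TTx clonotypes (5.93%, 3.98 to 8.46). All 5 untreated and all 26 TTx TRBV1 clonotypes were among these, since their CDR3 begins CTC. Without TRBV1 the counts were 2 of 55 (3.64%, 0.443 to 12.5) and 2 of 446 (0.448%, 0.0544 to 1.61), a count chosen after seeing the data. In the TRA CDR3, a cysteine was found in 0 of 14 untreated and 1 of 274 TTx clonotypes.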

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

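All tests in this part were chosen after the results were seen. Of the TRB contigs, 45.6% were not productive in the TTx library (95% interval 42.9 to 48.2) and 31.7% in the untreated library (22.8 to 41.7). TRB contigs with no V gene, which hold a J gene and no complete rearrangement, were 35.0% of TTx TRB contigs (32.5 to 37.6) and 22.8% of untreated ones (15.0 to 32.2). Both stood out because the share in the TTx tumor, in contigs that no comparison used, lay above the interval of the untreated tumor. These shares were not adjusted for depth, which was a median of 8 TCR UMIs per TTx barcode and 5 per untreated barcode. Their intervals count each contig of a barcode separately. Among the 491 TTx contigs with no V gene, 158 carried TRBJ2-1 and 103 carried TRBJ2-7. Without the barcodes of the largest TRB clone, 44.4% were not productive (41.6 to 47.1) and 32.8% had no V gene (30.3 to 35.5). Both shares still lay above the untreated interval, though the intervals then overlapped. Counted by barcode, a TRB contig with no V gene was present in 43.8% of TTx barcodes (40.3 to 47.4) and 28.6% of untreated ones (17.9 to 41.3), and these intervals overlapped as well. Of the TRA contigs, 29.3% (25.9 to 33.0) and 18.2% (5.19 to 40.3) were not productive, TTx first.

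The largest TRB clone of the TTx tumor, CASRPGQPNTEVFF, came with a TRA in 14 of 53 cells, or 26.4% (15.3 to 40.3), against 320 of 633 other TRB cells, or 50.6% (46.6 to 54.5). Among the 8 most frequent TTx TRB chains this share ran from 22.2% for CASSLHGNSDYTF (6.41 to 47.6) to 92.3% for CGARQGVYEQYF (74.9 to 99.1). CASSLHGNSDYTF thus had a share as low, but from 4 of 18 cells, and its interval overlapped that of the TRB cells other than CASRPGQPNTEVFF. Whether a low share was particular to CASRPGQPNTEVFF was therefore not settled. Free RNA caught in barcodes of other cells stays open: in the 39 cells without a TRA the chain had a lower quartile of 4 UMIs, but none of the 286 other barcodes with a single TRB chain and no TRA had 1 UMI, so the low values that free RNA would give were not seen among called cells of this kind at all. A single clone whose TRA was often not recovered is a candidate explanation: a TRBJ1-4 contig with no V gene was present in 33.3% of its TRA-less cells (19.1 to 50.2), in 9 of 14 of its cells with a TRA, and in 1.42% of other TRB cells (0.652 to 2.68), although free RNA of the clone could carry that contig too. Whether its TRA chain is poorly transcribed stays open as well, because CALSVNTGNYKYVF had a median of 2 UMIs (1.75 to 3) where found and other TRA chains of paired cells had a median of 3 (2 to 5). No explanation beyond these was tested.

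The TTx library held 12.2 times as many T cell barcodes as the untreated library. Shallower sequencing of the untreated library is argued against: a first test, on reads per barcode, could not tell because both libraries lay near a ceiling, but reads per UMI, which a ceiling can only lower, had a lower quartile of 8345 in untreated TRB contigs, so molecules of called cells were read many times over. Weaker capture of transcripts stays open: untreated TRB contigs had a median of 4 UMIs, below 6 in the TTx library, and barcodes under the cell call were not analysed here. The recombination of sorted cells at 2:1:1 would remove a difference in T cell density between the tumors as far as that ratio was met. Fewer T cells among those loaded or caught in droplets, and an effect of the treatment on what was recovered, cannot be told apart with 1 tumor per condition and no total cell number.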

How the results depend on the processing

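No paired analysis was possible because each condition had 1 tumor, so no replicate could be left out or matched either. Dropping the cell and confidence filter or asking for full-length contigs removed no productive contig, so these alternatives say nothing about stability. The authors' clonotype names are set per library, so they could not be used to count shared clonotypes. Of the recomputed values for the main results, 15 lay outside the counting interval of the value reported (or 1.5 times a count or correlation) and 69 lay within it; the cause was not tested beyond what each setting removes or regroups. Another 56 were not altered by the setting at all and are no evidence of stability. Lying within an untreated interval is weak evidence too, here and for single genes, because intervals from few cells are wide. The untreated largest clonotype went from 7.14% to 20% with at least 3 UMIs per contig and still lay within its interval. Mean TRB CDR3 length was 14.4 to 14.5 amino acids (untreated) and 13.8 to 14.0 (TTx) over its alternatives, and mean TRA length 13.6 to 14.3 and 13.6 to 13.7. The share of barcodes with both chains was 11.3% (untreated) and 34.3% (TTx) with at least 2 UMIs per contig, 9.09% and 26.5% with at least 3, and 30.1% for TTx at 3 UMIs per barcode; over barcodes with a TRB chain, a setting chosen after seeing the data, it was 48.7% for TTx. In each of these the TTx share was the higher one. The share of cells in expanded clonotypes moved to 38.2% (TTx) by the TRB chain alone, and to 42.7% (TTx) and 25% (untreated) by the TRA chain alone, and the largest TTx clone was 7.73% by TRB alone. At matched cell number the untreated value lay outside the range of the TTx draws for the TRB chain but not for the other definitions, with medians of 0 by paired chains and 12.5% by the TRA chain, where the untreated tumor had 25%. By the authors' clonotype column, which groups cells with 1 chain too, 30.8% of TTx and 6.35% of untreated cells were in clonotypes of 2 or more, and 63 drawn TTx cells had a median of 8 in them (2 to 15), beside 4 in the untreated tumor. By TRA nucleotides, 1 clonotype was shared between tumors; it rested on 1 UMI in the untreated tumor and may be carry-over between libraries, which was not tested. The iNKT-like share was 0 with at least 2 or 3 UMIs, which limits it to 1 molecule. With TTx clonotypes counted once, the TRBJ2 cluster was 65.9%. With the joined V entry as TRBV13-2, also chosen after seeing the data, the TRBV13 family was 16.0% of TTx cells. Of the recomputed values for single genes and other groups, 344 changed within their limit, 110 were not altered and 30 moved. With clonotypes counted once, 10 were lower and 3 higher, and with at least 3 UMIs per contig, 9 were lower and 1 higher. Under at least 1 alternative the order of the tumors turned for TRBV14, the TRBV12 family, TRAV6, TRAV7, TRAV14, TRAJ9, TRAJ16, TRAJ31, TRAJ2 to TRAJ20, TRAJ21 to TRAJ40 and the D or N copies of TRAV. Where the order turned, the untreated interval under that alternative held the TTx share, so the turned order lay within counting error. The turns followed from what the settings regroup or remove. For TRBV14, the TTx share fell from 12.1% of cells to 4.45% of clonotypes once each clonotype was counted once. For TRAJ9, TRAJ16 and TRAV14, the UMI minimum left no untreated cell with the gene.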

Other observations

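The chains in this part were chosen after their values were seen, as was the test of doublets. Several TTx receptors resembled one another while differing in nucleotide sequence. A pair of TRBV19 and TRBJ1-5 chains of the same length, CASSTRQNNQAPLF and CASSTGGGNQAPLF, were the dominant TRB of 15 and 12 cells, together 3.94% of TTx TRB cells (95% interval 2.61 to 5.68), and their main TRA partners both came from the TRAV6 family, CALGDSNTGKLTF in 9 cells and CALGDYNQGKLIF in 6. Whether the 2 TRB chains resembled each other beyond what their common V and J genes encode was not tested. TRAV6 was also the most used TRAV family of the TTx tumor, at 23.5% of TRA cells, and the partners differed in J gene (TRAJ27 and TRAJ23). In the untreated tumor 1 of 61 TRB cells joined TRBV19 to TRBJ1-5, with another CDR3. The TRB chain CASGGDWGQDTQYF was encoded by 2 nucleotide sequences, in 16 and 2 cells, whose TRA chains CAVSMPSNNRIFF (7 cells) and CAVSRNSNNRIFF (1 cell) both used TRAV7N-6 and TRAJ31. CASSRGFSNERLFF (TRBV26, TRBJ1-4) was encoded by 2 nucleotide sequences in 1 cell each, and both cells carried the TRA CDR3 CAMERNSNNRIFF, again in 2 nucleotide forms.

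The TRA chain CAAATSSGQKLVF, found in both tumors, came with several TRB chains. In the untreated tumor, where it rested on 1 UMI in each of 2 cells, these were the TRBV1 chain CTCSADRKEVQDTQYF and the TRBV31 chain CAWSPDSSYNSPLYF. In the TTx tumor, 3 of its 4 cells held the TRBV10 chain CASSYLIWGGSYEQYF, 2 of these also held the TRBV31 chain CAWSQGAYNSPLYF, and the other cell held no TRB chain.

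Pairs of chains recurred in TTx barcodes that held 2 chains of 1 kind. Of 77 such barcodes with 2 TRB chains, 11 held 1 of 3 recurring pairs, led by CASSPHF with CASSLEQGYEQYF in 6 barcodes and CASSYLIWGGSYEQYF with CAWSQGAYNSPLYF in 3. Of the 50 barcodes with 2 TRA chains, 10 held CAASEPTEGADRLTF with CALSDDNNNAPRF, and 6 of these 10 held the TRB chain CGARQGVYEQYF. With other TRB chains and without that one, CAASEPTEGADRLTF was found in 4 barcodes and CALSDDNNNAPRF in 3, each out of 26. As a hypothesis, these may mark 1 clone with 2 productive TRA chains. Among the 26 barcodes with that TRB chain and a TRA, both TRA chains were found in 23.1% (8.97 to 43.6), overlapping the 9.74% of other paired barcodes with 2 TRA chains (6.67 to 13.6), a comparison set before its result was seen that did not decide. The count of barcodes argues against random doublets of 2 separate clones, since 10 barcodes with both chains (Poisson interval 4.80 to 18.4) lay above the 0.310 expected from random pairs. The pair was picked because it recurred, and other ways for both chains to reach 1 barcode were not tested.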
